A study of Mus musculus with 8 samples.

How the data were processed

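Gene expression in mouse visual cortex had been measured on 8 Affymetrix short-oligonucleotide arrays, 4 for deprived and 4 for non-deprived cortex. Per the labels, 5 wild-type C57BL/6 mice lost an eye on postnatal day 42 and their visual cortex was taken 4 days later, on day 46, from coronal sections 1 mm thick. About 10 µg of total RNA went into the biotin-labelled target. Deprived cortex lay contralateral and non-deprived cortex ipsilateral to the missing eye. The series design calls the samples pooled. The labels do not say which mice entered which pool, so the p-values here measure the spread between these samples, which may be technical.

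The table the authors deposited holds 12488 probe sets with 1 intensity per array on a linear scale, made with MAS5 per the submitters' processing notes. The MAS5 version is not given in the sources used here. Detection calls were not used here. The 2%-trimmed mean of the deposited intensities was 500.2 to 500.3 on all 8 arrays, so the arrays had been scaled to a common level and the values were used as deposited. The largest trimmed mean was 1.0002 times the smallest, against a limit of 1.1 above which quantile normalization would have been used.

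Values were analysed as log2(signal + 16.3), where 16.3 was the 10th percentile of all deposited values. Differences on this scale understate the change of dim probes. The 66 control probe sets and the 40% of the other 12422 probe sets with the lowest mean log2 value were left out, which left 7453. Genes were named from the GEO platform annotation, with symbols updated through Entrez identifiers against the RefSeq gene table. Of the 7453 probe sets, 6736 had 1 gene, 245 had several and were not used to name a gene, and 472 had no gene listed. They covered 5687 genes, 914 of them through several probe sets. A gene with several probe sets was represented by the brightest. No genome coordinates were used.

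Deprived and non-deprived arrays were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over the 7453 probe sets and a threshold of 0.05. All differences are deprived minus non-deprived. Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists with at least 5 measured genes, and again with the correlation estimated per list. The fry test of limma was run beside it. The mean of each list per array was also compared by an exact two-sided permutation test over the 70 ways to pick 4 of 8 arrays, whose smallest p is 0.0286. The lists were written before the data were examined, as were the tests and most of the other settings tried. They numbered 35, with 692 genes, of which 389 were measured. The lists of neurotrophins and their receptors, striatal markers, and cholinergic and monoaminergic receptors had 3, 4 and 4 measured genes and were not tested, which left 32.

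The genes named were chosen by a rule set before the data were examined. It took up to 15 genes highest and 15 lowest in deprived cortex among those whose probe passed the threshold. Where fewer than 5 passed in a direction, the genes with the lowest p in that direction were added up to 10 and given as values only. It also took up to 4 genes with the lowest p in each list described, and a fixed set (Egr1, Fos, Fosb, Junb, Arc, Nr4a1, Bdnf, Homer1, Dusp1, Dusp6, Nptx2, Nrn1, Gfap, H2-K1, H2-D1, B2m, Gapdh, Actb). No probe set was named for Arc or Nrn1 alone, and Gapdh was named only with other genes, so these 3 are not reported as genes. Gadd45b and Klf10 were named in addition because a probe set other than the brightest passed.

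RNA integrity was followed by the ratio of the 3' to the 5' control probe sets of Actb and Gapdh, and the low end of each array by its 10th percentile and by 19 probe sets for bacterial and yeast sequences. Other settings changed the pseudocount, the filter on dim probe sets, the normalization, the variance model, the array weights, the threshold and the use of replicate number as a block, and left out each array in turn. For the lists they also changed the correlation, the test and the gene representative. Further settings were added after the data had been seen: quantile normalization or the replicate block together with leaving out deprived replicate 3, and adjustment over 1 probe set per gene. The number of arrays limits the precision of every value.

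The fit was tested on simulated arrays with the real means and spreads of the 7453 probe sets, 4 arrays against 4, in 5 runs with 200 changed probe sets each. It called 14.9% of probe sets changed by 0.5 on the log2 scale, 62.7% of those changed by 1 and 93.3% of those changed by 2, and 5.80% of all calls were false. The real arrays gave only 7 calls, and with fewer calls the adjusted threshold demands a smaller p. The shares called in the simulation can thus be higher than those on the real arrays. A list of immediate early genes lowered by 0.5 was called in 5 of 5 runs, and 1 of 145 tests of other lists passed. The lists of activity-regulated effector genes and of MAP kinase phosphatases were not among those other lists. These simulated genes varied independently, so the rate of list calls need not hold on the real arrays. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.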

Results

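Gene expression was compared between the visual cortex opposite a removed eye (deprived) and the visual cortex on the same side as that eye (non-deprived) in mice at postnatal day 46, 4 days after the eye was removed. In mice most optic nerve fibres cross the midline, so the contralateral cortex loses most of its visual input. Each group had 4 arrays. The series holds no cortex from mice with both eyes, so a lower deprived level cannot be told from a higher non-deprived level. The median signal per array lay between 178.3 and 254.9, and 7453 probe sets for 5687 genes were bright enough to be tested.

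The clearest difference was a lower level of genes that neurons induce within minutes to hours of activity. Fos, a leucine-zipper transcription factor used as a marker of neuronal activity, had a signal of 804.4 ± 131 (SD, n = 4) in deprived and 3516 ± 608 in non-deprived cortex, 4.29-fold lower on the log2(signal + 16.3) scale (log2 difference −2.10 ± 0.18 SE, limma adjusted p = 0.0011). The orphan nuclear receptor Nr4a1 was 3.50-fold lower (1069 ± 135 against 3764 ± 320, adjusted p = 0.0011). The zinc-finger transcription factor Egr2 was 3.29-fold lower (349.3 ± 54.6 against 1180 ± 102, adjusted p = 0.0011). Egr1 had a signal of 3064 ± 687 in deprived and 7805 ± 889 in non-deprived cortex (log2 difference −1.37 ± 0.18, adjusted p = 0.027). Ptgs2, the inducible cyclooxygenase, had 84.7 ± 11.7 in deprived and 213.1 ± 28.7 in non-deprived cortex (log2 difference −1.18 ± 0.15, adjusted p = 0.019). On deprived replicate 3 the Ptgs2 signal was 85.0, near the median of 83.3 of the bacterial and yeast probe sets on that array. Without that array the log2 difference of Ptgs2 was −1.19.

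**Figure D1:**
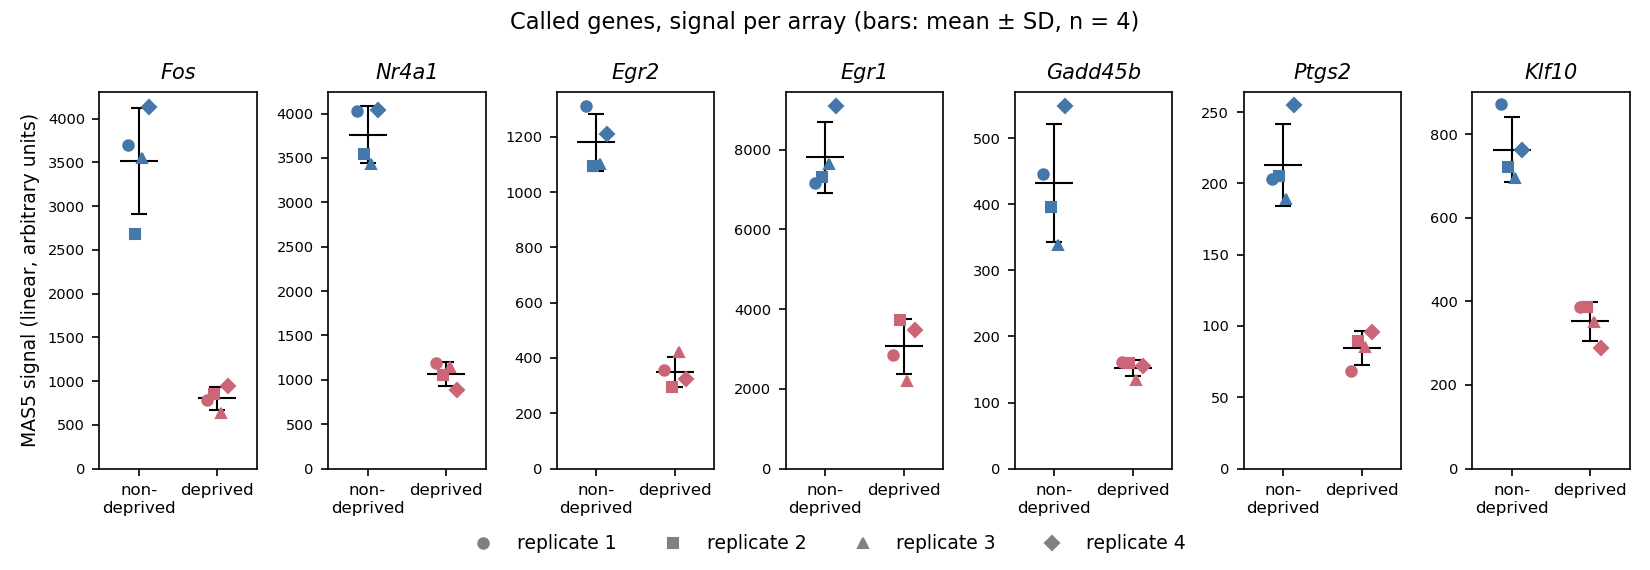
MAS5 signal (linear axis from 0) of the 7 genes that passed the threshold, for each of the 4 non-deprived (blue) and 4 deprived (red) arrays, with the mean and SD; marker shapes give the replicate number. For Gadd45b and Klf10 the probe set that passed is drawn. In each panel the 4 deprived arrays lie below the 4 non-deprived arrays; for Fos the means were 804.4 and 3516.

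In all, 7 probe sets for 7 genes passed, 7 lower and 0 higher in deprived cortex. The remaining 2 were Gadd45b, a stress- and activity-inducible gene, and the zinc-finger transcription factor Klf10. Each passed through a probe set that was not its brightest: −1.39 ± 0.16 for Gadd45b (adjusted p = 0.014) and −1.08 ± 0.14 for Klf10 (adjusted p = 0.027). Their brightest probe sets gave −0.91 (adjusted p = 0.44) and −0.94 (adjusted p = 0.16). The 2 Gadd45b probe sets were about equally bright, with mean log2 values of 8.09 and 8.09. All 7 genes belonged to the 2 lists of activity-regulated genes described next. At an unadjusted p under 0.05 there were 268 probe sets lower and 269 higher, against 373 in total by chance. Nr4a1, Egr2 and Fos passed whichever array was left out. Klf10 did not pass whichever array was left out (adjusted p from 0.051 to 0.14). Egr1 and Ptgs2 passed only without deprived replicate 3 (up to 0.14 and 0.096 otherwise), and Gadd45b only without deprived replicate 3 or non-deprived replicate 3 or 4 (up to 0.094 otherwise). With no filter on dim probe sets, Nr4a1, Egr2 and Fos alone passed. Quantile normalization ended the calls of Ptgs2 (0.25) and Gadd45b (0.12), the trended robust variance that of Ptgs2 (0.091), and the stricter filter removed the probe sets of both before testing. The count fell to 3 without non-deprived replicate 1 or 2 or deprived replicate 1, 2 or 4, and to 4 without non-deprived replicate 3 or 4.

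No gene passed in the higher direction. The 10 genes with the lowest p there had values of 0.83 ± 0.18 for Abhd17a, 0.77 ± 0.17 for H2-DMb2, 0.77 ± 0.19 for Trpm1 and 0.75 ± 0.16 for the fatty acid-binding protein gene Fabp5, with adjusted p from 0.34 to 0.45. Abcb8, Dolpp1, Zfp472, the clock output gene Dbp, Grhpr and Syt17 had differences from 0.45 to 0.62. A second probe set of Abhd17a gave 0.18.

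The immediate early transcription factors, the first wave of genes switched on by synaptic activity, were lower as a group. Of 17 measured, 14 had a negative and 3 a positive difference, with a median of −0.52 (camera adjusted p = 9.0e-11, and adjusted p = 0.069 with an estimated correlation). Fos, Nr4a1, Egr2 and Egr1 passed over all genes tested, and 9 members passed adjusted over the list alone, all 9 lower. Fosb (−0.67 ± 0.19) and Junb (−0.74 ± 0.25) did not pass over all genes. A second Junb probe set gave −1.51 ± 0.37.

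The activity-regulated effector genes, which encode secreted, synaptic and signalling proteins, were lower too. Of 18 measured, 16 had a negative difference and 2 a positive, with a median of −0.31 (camera adjusted p = 3.1e-07, and adjusted p = 0.069 with an estimated correlation). Ptgs2 alone passed over all genes through its brightest probe set, and 5 members passed adjusted over the list alone. Values of the others were −0.83 ± 0.13 for the secretogranin gene Scg2 (adjusted p = 0.076) and −1.26 ± 0.24 for the neurotrophin gene Bdnf (adjusted p = 0.20), whose signal on non-deprived replicate 4 was 3427 against 1966 to 2048 on the rest of that group. Homer1, which encodes a postsynaptic scaffold protein, gave −1.17 ± 0.52 and the pentraxin gene Nptx2 gave −0.49 ± 0.22. The Homer1 signal was 47.7 and 20.1 on deprived replicates 3 and 4, near the low end, against 158 and 181.7 on deprived replicates 1 and 2. With an array left out its difference ranged from −1.52 to −0.71. For the mean of each list per array, the exact permutation p was 0.0286, the smallest these arrays can give, and 7 of the 32 lists reached it (adjusted p = 0.13). Besides both activity lists, the means of interneuron markers, deep cortical layer markers, cholesterol synthesis and the glucocorticoid response did so on the lower side, and the meninges and choroid plexus on the higher side.

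**Figure D2:**
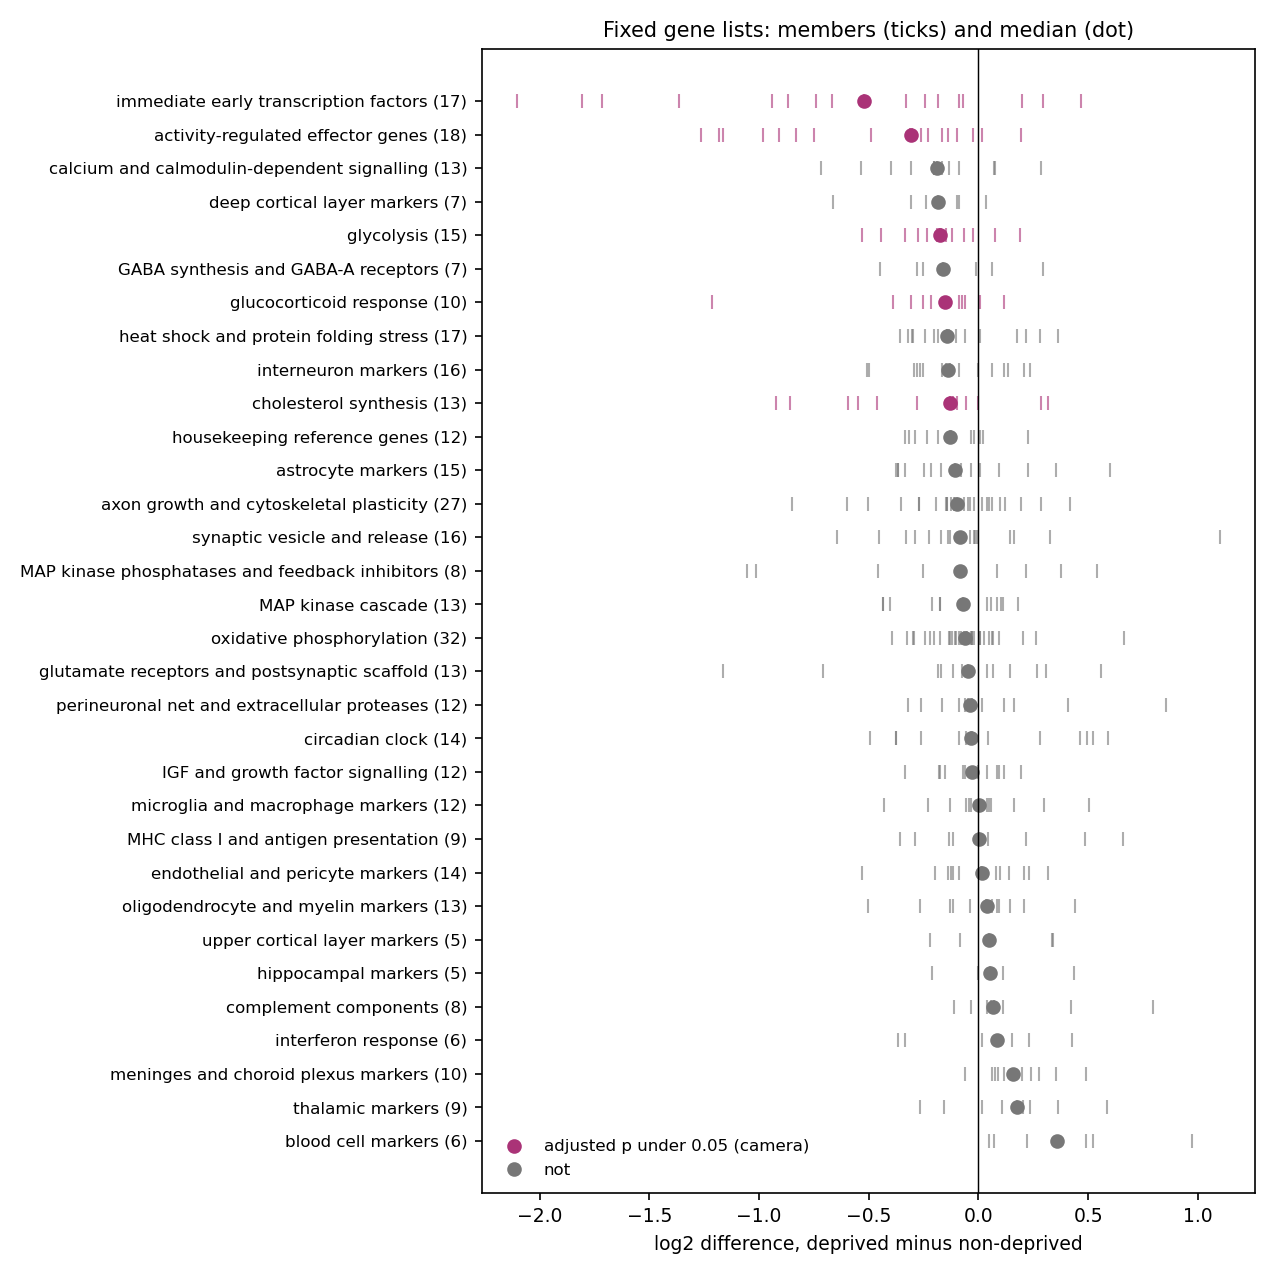
Log2 difference (deprived minus non-deprived, horizontal axis) for each measured member (ticks) and the median (dots) of the 32 gene lists, with the number of measured members in parentheses; purple marks an adjusted camera p under 0.05. The immediate early transcription factors lie farthest left, with a median of −0.52, and the blood cell markers farthest right, with a median of 0.36.

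The MAP kinase phosphatases and feedback inhibitors, which switch off signalling that activity turns on, did not pass as a list. Among 8 measured members 4 were negative and 4 positive (median −0.08, camera adjusted p = 0.087, and adjusted p = 0.39 with an estimated correlation). It passed without deprived replicate 3 (adjusted p = 0.045), without non-deprived replicate 1 (0.044), with array weights (0.042), and with quantile normalization without deprived replicate 3 (0.049). Its median was nearer to zero without deprived replicate 3, at −0.045. With no filter on dim probe sets its median was 0.09, while camera's direction stayed downward (0.058). The median over all probe sets was 0.13 in that setting. Adjusted over the list alone, 3 members were lower, and 0 passed over all genes. Dusp1 gave −1.06 ± 0.16 (adjusted p = 0.076), Dusp6 gave −1.01 ± 0.18, Spred2 gave −0.46 and Errfi1 gave −0.25 (−0.15 without deprived replicate 3).

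Cholesterol synthesis genes were lower as a list. Of 13 measured, 11 had a negative and 2 a positive difference, with a median of −0.13 (camera adjusted p = 0.012, and adjusted p = 0.14 with an estimated correlation). The median was −0.22 without non-deprived replicate 4 and −0.23 without deprived replicate 4. No member passed over all genes tested and 3 passed adjusted over the list alone, all lower. The values were −0.86 ± 0.16 for Hmgcs1, the cytosolic HMG-CoA synthase gene, −0.92 ± 0.23 for Msmo1, −0.59 ± 0.12 for Idi1 and −0.55 ± 0.22 for Cyp51. Without deprived replicate 3 the median was −0.17. Hmgcs1 (−0.75), Msmo1 (−0.69) and Cyp51 (−0.37) were nearer to zero there, and Idi1 (−0.64) was farther from it.

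Glycolysis genes (13 of 15 negative, median −0.17, camera adjusted p = 0.031) and glucocorticoid-responsive genes (8 of 10 negative, median −0.15, adjusted p = 0.032) also passed. With an estimated correlation the adjusted p was 0.59 for glycolysis and 0.39 for the glucocorticoid list. In the glycolysis list 0 members passed, over all genes or adjusted over the list alone; lactate dehydrogenase A (Ldha) gave −0.44 ± 0.12, the glucose transporter gene Slc2a1 −0.53 ± 0.22, Pgk1 −0.33 and Pfkp −0.27. In the glucocorticoid list 1 member passed adjusted over the list alone and 0 over all genes. That was the cell cycle inhibitor gene Cdkn1a (−1.22 ± 0.24), which is not specific to glucocorticoids and whose second probe set gave 0.24 ± 0.38. Zbtb16 gave −0.39, Sgk1 −0.31 and Errfi1 −0.25 (−0.15 without deprived replicate 3). Without deprived replicate 3 the glycolysis median was −0.05, with Pgk1 at −0.11 and Slc2a1 at −0.32, so much of its size came from that array. The call was lost without it (adjusted p = 0.22), and without deprived replicate 4 (0.073), non-deprived replicate 2 (0.054) or non-deprived replicate 3 (0.062). The glucocorticoid call was lost when any array other than deprived replicate 4 was left out, with adjusted p up to 0.41, and its median was −0.03 without non-deprived replicate 2 and −0.05 without non-deprived replicate 4.

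Genes of immune recognition and of glia did not pass. The MHC class I list had a median of 0.0027 over 9 genes (adjusted p = 0.94). H2-K1 gave 0.0027 ± 0.16 and H2-D1 0.04 ± 0.18, both with signs that turned under median centring, and for H2-K1 also under quantile normalization. B2m gave −0.29 ± 0.20 (−0.46 to −0.17 with an array left out), Tapbp 0.22 and Psmb10 −0.13. H2-Q10 gave 0.66 ± 0.25 (614.1 on deprived replicate 3, at most 285.5 on the other deprived arrays). The probe sets of H2-K1 and H2-D1 can bind several members of this gene family. Microglial markers had a median of 0.0015 (adjusted p = 0.96), with 0.50 ± 0.29 for Cx3cr1, 0.30 for Cd14, −0.43 for Cd53 and −0.23 for Csf1r. Astrocyte markers had a median of −0.11 (adjusted p = 0.30), with 0.60 for Vim, −0.36 for S100b, 0.35 for Id3 and −0.25 for Sparcl1. Gfap gave 0.10 ± 0.21, and 0.35 ± 0.18 with a second probe set. Oligodendrocyte markers had a median of 0.04 (adjusted p = 0.94), with 0.44 for Myrf, −0.50 for Ugt8a, −0.27 for Car2 and 0.21 for Sox10. A second probe set gave 0.38 for Csf1r and −0.25 for Sox10. Several of these values were smaller without deprived replicate 3, where Cx3cr1 gave 0.25, Cd14 0.19, Csf1r −0.12, Id3 0.20, Sparcl1 −0.14, Myrf 0.27, Car2 −0.15, Sox10 0.04, Psmb10 −0.08 and H2-Q10 0.38. Gfap was larger there, at 0.25, and the MHC class I median was 0.11.

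Neuronal class markers did not pass either, but with no filter on dim probe sets the interneuron list passed on the lower side (adjusted p = 0.013). With an estimated correlation and the dim probe sets left out, its adjusted p was 0.39. With no filter the median difference over all probe sets was 0.13, and camera compares a list with all other genes. Interneuron markers had a median of −0.14 over 16 genes (adjusted p = 0.10), with −0.51 ± 0.14 for the neuropeptide gene Cort, −0.50 for Tac1, −0.29 for Npy and −0.28 for Gad1. Deep cortical layer markers had a median of −0.18 over 7 genes (adjusted p = 0.087), with −0.66 for Tle4, −0.31 for Tbr1, −0.24 for Ccn2 and −0.18 for Nr4a2. Synaptic vesicle genes had a median of −0.08 (adjusted p = 0.82). Actb, which encodes beta-actin, gave −0.18 ± 0.32 (0.06 with a second probe set, and −0.53 to −0.02 with an array left out). Without deprived replicate 3 the medians were −0.09 for interneuron, −0.10 for deep layer and −0.01 for synaptic vesicle genes, and 0.0017 for the astrocyte markers. Tac1 gave −0.31 there, Ccn2 −0.10 and Nr4a2 −0.34. Over all arrays left out in turn, Nr4a2 ranged from −0.34 to −0.025.

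Markers of blood cells and of the meninges and choroid plexus leaned the other way. All 6 measured blood cell genes were positive, with a median of 0.36 (camera adjusted p = 0.087), and the list passed without deprived replicate 3 (adjusted p = 0.045) or non-deprived replicate 3 (0.041). It also passed with no filter on dim probe sets (0.013), array weights (0.022) and the mean of all probe sets (0.034). With an estimated correlation the adjusted p was 0.39 for the blood cell list and 0.36 for the meninges and choroid plexus list. For the meninges and choroid plexus, 9 of 10 genes were positive, with a median of 0.16 (adjusted p = 0.087), and the list passed with array weights (0.031). Without deprived replicate 3, both lists passed with quantile normalization (0.049 and 0.049), a setting added after the data had been seen. Thalamic markers were positive for 7 of 9 genes, with a median of 0.17 (adjusted p = 0.19), which was 0.04 without deprived replicate 3, 0.07 and 0.11 without non-deprived replicate 4 or 3, and 0.29 without deprived replicate 4.

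The arrays differed in their low and high signals. On deprived replicate 3 the 10th percentile of signal was 62.7, against 12.3 to 17.9 on the other 7 arrays, and 0.52% of probe sets lay at or below 16.3, against 9.07% to 13.2%. At the high end its 99th percentile was 6178, against 7990 to 9022 on the other 7 arrays. Its signals were thus compressed at both ends, which can lower bright genes in the deprived mean. Its median correlation with the other arrays was 0.902, against 0.968 to 0.977 for the rest. The mean log2 ratio of 3' to 5' signal of Actb and Gapdh was 0.76 ± 0.24 (SD, n = 4) in deprived and 0.78 ± 0.38 in non-deprived cortex, a difference of −0.02 (exact permutation p = 1).

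**Figure D3:**
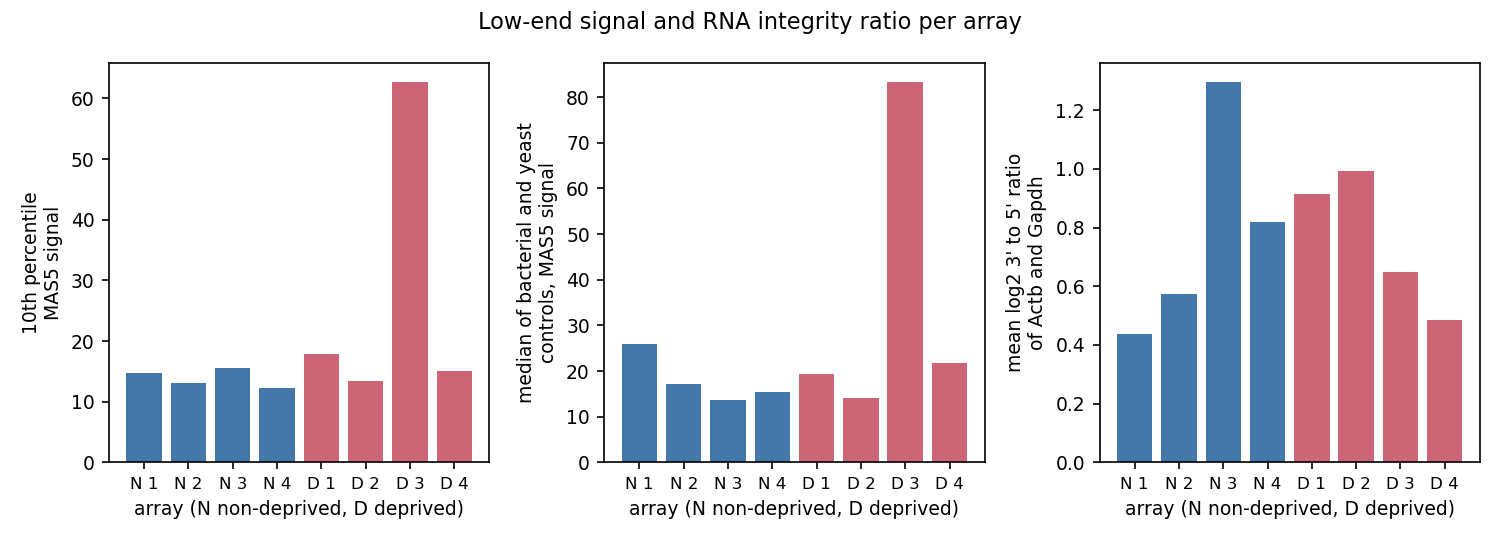
Per array (4 non-deprived in blue, 4 deprived in red), the 10th percentile of MAS5 signal, the median MAS5 signal of 19 bacterial and yeast control probe sets, and the mean log2 ratio of 3' to 5' signal of Actb and Gapdh; each bar is 1 array. Deprived replicate 3 stands at 62.7 and 83.3 in the panels of low signal, above the other 7 arrays, and at 0.65 in the panel of the ratio, inside their range.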

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

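Apart from the counts over other splits of the arrays, the tests in this part were chosen after the result was seen. In 240 groups of 4 arrays (120 genes, list means and array measures, each in 2 groups), 9 held an array far from the other 3, where chance gives about 12. Of the 9, 6 were on deprived replicate 3. Its 10th percentile of signal was 62.7 (others in its group 13.4 to 17.9), its bacterial and yeast control median was 83.3 (14.0 to 21.8), and its median correlation with other arrays was 0.902 (0.968 to 0.976). On that array H2-K1 was low, at 584.9 (814.8 to 860.8), Nr4a2 was high, at 323.7 (195.4 to 211.3), and H2-Q10 was high, at 614.1 (263.1 to 285.5). Bdnf stood at 3427 on non-deprived replicate 4 (1966 to 2048 on the others of its group). Ldha was at 5585 on non-deprived replicate 4 (6094 to 6149), and Cort at 302.8 on non-deprived replicate 1 (341.8 to 347).

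The raised low signals of deprived replicate 3 may come from a raised background on that array. Its control probe sets for bacterial and yeast sequences had a median 3.20 times the highest of the other arrays, and 18 of 19 were highest there. The labels do not say whether such sequences were added to the samples. A wrong group label is argued against: on 6 of the 6 probe sets called from the other 7 arrays, deprived replicate 3 lay nearer to the deprived mean. A difference in how that array was washed, scanned or processed was not tested, and no biological explanation was tested.

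Activity-regulated genes were lower in deprived cortex, the design's contrast of visual input. The 7 called probe sets are unlikely to come from a chance split of the arrays: 1 of the 35 splits of the 8 arrays, the real one, called as many, and the highest of the others called 1. No smaller share than 1 of 35 is possible. The splits also treat the 8 samples as independent, which the labels leave open. Over the 35 measured members of both activity lists, the median was −0.33. It was −0.55 without deprived replicate 3, which argues against that array as the cause. RNA integrity is argued against as the whole cause: the mean of these genes differed by −0.56, and at the ends of the 95% intervals of its slope and group difference that lower the mean most, the 3' to 5' ratio accounts for −0.22. Fewer neurons would lower other neuronal genes as much. However, 73 genes of 7 neuronal lists (without Homer1 and Nr4a2, also activity genes) had a median of −0.12 (96.6% interval −0.17 to −0.02). That interval treats genes as independent and does not measure the spread between samples. Without deprived replicate 3 the full lists had medians of −0.10 (deep layer), −0.09 (interneuron), −0.07 (calcium) and −0.03 (GABA). Synaptic vesicle genes had −0.01, upper layer markers 0.04 and glutamate receptors 0.07 there. A smaller neuronal share stays open as a part. With no filter on dim probe sets the interneuron (0.013) and calcium signalling (0.011) lists passed on the lower side. In that setting the median difference over all probe sets was 0.13, against 0.0082 with the filter. Camera compares a list with all other genes, so these passes cannot tell a fall in neurons from a rise of the other probe sets. The order of dissection was not tested and stays open beside the loss of input.

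The count of called lists is weaker evidence. Of the 35 splits, 2 called 5 or more lists, the highest of the others called 7, and 27 called at least 1, so chance cannot be excluded for this count. By list, the real split alone gave a camera p as small for the immediate early transcription factors, the effector genes and cholesterol synthesis. Their unadjusted camera p was 2.8e-12, 2.0e-08 and 0.0011, and the lowest of any other split was 1.9e-10, 5.0e-07 and 0.012. A very small camera p alone thus does not set the real split apart, and 1 of 35 is the smallest share this count can give. For glycolysis 6 of 35 splits did so, and for the glucocorticoid list 2 of 35.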

How the results depend on the processing

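Added after the data had been seen were adjustment over 1 probe set per gene, and deprived replicate 3 left out together with quantile normalization or the replicate block. The count of 7 called probe sets became 3 with no filter on dim probe sets, 12 with array weights and 3 with the replicate block, with or without deprived replicate 3. It ranged from 3 to 6 with an array left out. All calls under these settings were lower in deprived cortex, and the same 3 probe sets (Nr4a1, Egr2, Fos) were called in each. Genes called in addition included Serpina3n, Scg2, Dusp6, Idi1 and a second Klf10 probe set with array weights, Serpina3n, Dusp1 and Scg2 with the stricter filter, Dusp1 and Scg2 with the trended robust variance, and Dusp1 with the larger pseudocount. Calls lost included Ptgs2 and Gadd45b with quantile normalization, Ptgs2 with the trended robust variance, and both with the stricter filter, which left their probe sets untested. Whether equal replicate numbers share mice is unknown. It was looked at through the arrays' deviations from their group means, not their signals. Correlations of these deviations between same-numbered arrays ran from −0.0040 to 0.39 (2 of 4 above 0.1, and at most 0.14 for other numbers). By this measure 4 of 8 arrays correlated best with their own number.

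The 5 called lists became 11 with no filter, 2 with the stricter filter, 3 with quantile normalization, 3 with fry and 0 with an estimated correlation, and 3 to 6 with an array left out. With no filter the lists were tested against a raised reference, the median difference over all probe sets being 0.13. The replicate block kept 5, and with it and no deprived replicate 3 the blood cell (0.0012) and meninges (0.030) lists were called higher. The immediate early and effector lists lost their call only with the estimated correlation (adjusted p 0.069 and 0.069). Cholesterol synthesis lost it there (0.14) and with the stricter filter (0.052). Glycolysis had 0.054 with the stricter filter, 0.30 with quantile normalization and 0.34 when deprived replicate 3 was left out as well, 0.18 with array weights, 0.49 with the replicate block and no deprived replicate 3, 0.59 with an estimated correlation and 0.43 with fry (0.0090 to 0.22 with an array left out). The glucocorticoid list had 0.13 with the stricter filter, 0.30 with quantile normalization and 0.075 without deprived replicate 3 as well, 0.39 with an estimated correlation, 0.15 with fry and 0.053 with the mean of all probe sets (0.029 to 0.41 with an array left out). The cause was not tested.

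Among 1635 values of 83 genes or probe sets under other settings, 19 turned sign, for 6 genes, none of them called. H2-K1 became −0.018 with quantile normalization and −0.044 with median centring, and ranged from −0.055 to 0.13 with an array left out. H2-D1 became −0.0042 with median centring, −0.049 with array weights and −0.047 with quantile normalization without deprived replicate 3 (−0.052 to 0.17). Gfap ranged from −0.033 to 0.25. With the replicate block and no deprived replicate 3, Actb was 0.0037 and Sox10 −0.016. With the mean of all probe sets Sox10 was −0.024 and Csf1r 0.075. The difference in the 3' to 5' ratio ranged from −0.14 to 0.15 with an array left out, and the middle to 5' ratio gave 0.0041. The 40% of probe sets with the lowest mean log2 value in a setting were tested only with no filter. With another pseudocount or with quantile normalization that 40% was chosen anew.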

Other observations

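Circadian clock genes had values in both directions, and their list had no net shift: 8 of 14 measured genes were negative and 6 positive (median −0.03, camera adjusted p = 0.94, camera's own direction upward). The fry test for change in either direction gave an adjusted p of 0.0025, and was not repeated over the other splits of the arrays. Dbp, which encodes a transcription factor that follows the clock, gave 0.52 ± 0.13 and Bhlhe40 gave −0.50 ± 0.14, both passing adjusted over the list alone. Nr1d1 (0.59 ± 0.22) and Tef (0.47 ± 0.19) had positive values, and the next by p, Per2 (−0.37 ± 0.16) and Clock (−0.38 ± 0.17), negative ones. In fry's test of either direction 5 of 32 lists passed, the others being both activity lists, the MAP kinase phosphatases (adjusted p = 0.0023) and cholesterol synthesis (0.024). None of the 4 clock genes with the lowest p passed over all genes.

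No gene outside the 35 lists passed over all genes. The 5 with the lowest p, chosen after their values were seen, are given here. The lowest p belonged to Serpina3n, a serine protease inhibitor gene made by reactive astrocytes, with −1.16 ± 0.19 (adjusted p = 0.090); it passed with the stricter filter on dim probe sets (0.033) and with array weights (0.047). Kat2a gave −1.06, Fgf12 −0.85, Sertad1 −0.79 and the imprinted gene Mest −0.77, with adjusted p from 0.20 to 0.25. Each of these 5 had its 4 deprived arrays below the 4 non-deprived arrays. Choosing genes by their low p favours such a separation, so it adds no support.

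The other lists did not pass. With no filter on dim probe sets, calcium signalling (adjusted p = 0.011), axon growth (0.013), housekeeping genes (0.044) and oxidative phosphorylation (0.049) passed on the lower side, the last also without non-deprived replicate 1 (0.022). With an estimated correlation and the dim probe sets left out, their adjusted p was 0.55, 0.89, 0.59 and 0.96, in that order. With no filter the median difference over all probe sets was 0.13, so a list without any fall can test as lower there. Calcium and calmodulin-dependent signalling had a median of −0.19 (adjusted p = 0.090), GABA synthesis and GABA-A receptors −0.16 (0.26), heat shock and protein folding −0.14 (0.25), housekeeping reference genes −0.13 (0.22) and axon growth −0.10 (0.25). Without deprived replicate 3 these medians were −0.07, −0.03, −0.04, −0.06 and 0.0047, in that order. The MAP kinase cascade had −0.07 (0.30), oxidative phosphorylation −0.06 (0.25), glutamate receptors −0.05 (0.74) and IGF and growth factor signalling −0.03 (0.87). Perineuronal net genes had −0.04 (0.94, camera's direction upward), and endothelial markers 0.01 (0.94, camera's direction downward). Upper cortical layer markers had 0.05 (0.96), hippocampal markers 0.05 (0.94), complement 0.06 (0.40) and the interferon response 0.08 (0.94). Without deprived replicate 3 the medians of oxidative phosphorylation (0.04), glutamate receptors (0.07), endothelial markers (−0.02) and the circadian clock (0.01) turned sign, and those of complement and hippocampal markers were 0.01 and 0.09.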
